A study of Arabidopsis thaliana with 4 samples.

How the data were processed

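Gene expression was measured in 4 Affymetrix ATH1 arrays, which are one-colour oligonucleotide arrays hybridised with biotin-labelled RNA. Each array held total RNA of whole Arabidopsis thaliana plants. The labels put 2 arrays in the wild type gl1 group and 2 in the 35S::ZAT12 group. In the latter the ZAT12 zinc finger gene is expressed from the 35S promoter. Source names give gl1 for the first group and only 35S::ZAT12 for the second, so they do not state whether the overexpressors carry gl1. A difference in background could not be told apart from an effect of the transgene. Per the labels' protocols, plants grew for 10 days at 24 °C in continuous light of 100 µmol per m2 per s on 0.80% phytagar with Gamborg's B5 salts, after 4 days at 4 °C. Those protocols also state that 4 plates of about 100 plants per genotype were harvested individually. They do not tie plates to arrays, so p-values measure the spread between these arrays, which may be partly technical. The titles of the overexpressor arrays carry different line codes (P15-15A and P15-8B), while the growth text of both names p15-8. Whether the 2 arrays hold 1 transgenic line or 2 was left open.

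The deposited values are signal intensities on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes; its version and the detection calls are not given in the sources used here. The mean after leaving out the lowest and highest 2% of probe sets was 100.009 on the wild type arrays, 100.008 on 35S::ZAT12 replicate 1 and 100.009 on 35S::ZAT12 replicate 2, so each array had been scaled to one target. No value was missing, 0 or negative. The number of arrays limits the precision of every value.

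The deposited intensities were log2 transformed with no pseudocount and no further scaling. Of 22810 probe sets, 64 controls were left out. A probe set was tested if it lay above its array's 40th percentile on both arrays of at least 1 genotype, which left 13701 (60.2% of the rest). The contrast 35S::ZAT12 minus wild type was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 2 residual and 8.97 prior degrees of freedom. The limma and camera tests were two-sided. Counts of neighbouring genes called together were read one-sided, as the share of random draws with at least as many, without adjustment for the 2 kinds of pair counted. Adjusted p-values are Benjamini-Hochberg values over the probe sets tested, with a threshold of 0.05. A second count, which rests on no variance estimate, took the probe sets that differed at least 2-fold in one direction in all 4 pairings of an overexpressor with a wild type array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

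Probe sets were named from the platform gene table. It paired 13513 probe sets with 1 gene and 503 with several, and 8730 others were unnamed here; 7331 of the tested probe sets had 1 gene. Of the one-gene probe sets, 13436 matched the RefSeq annotation of assembly TAIR10.1 through their Entrez identifier, which gave loci and gene order. A probe set with several genes was given no name. Where a gene had more than 1 probe set (146 genes), list tests used the one with the highest mean. ZAT12 was paired with 0 probe sets in this table and is not analysed here.

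The rule for named genes, the tests and 17 gene lists (262 genes) were fixed before the data were examined. The named genes are the 12 largest rises and the 12 largest falls among one-gene probe sets past the threshold, and up to 4 members of each list by absolute log2 fold change. Only 37 of the list genes had a one-gene probe set and 29 of these were tested, so 6 lists reached the minimum of 3 tested members. A further 22 gene families, defined by gene symbol, were added after the gene table had been read but before any genotype difference was looked at. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over all 28 lists and families tested.

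Without detection calls, the 27 bacterial control probe sets (dap, lys, phe, thr and trp) served as a stand-in for background. Their highest value per array lay between 7.87 and 14.4. A probe set at or below that value on both arrays of a genotype is called in the background there. Its fold is given as a bound, the brighter genotype's mean log2 signal against the mean of the array's highest bacterial control.

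The scripts were tested on simulated arrays for the comparison of 35S::ZAT12 with wild type, over 13701 probe sets of which 200 were changed. At a 4-fold change 92.5% were recovered with 4 false calls among 189. At a 2-fold change 23% were recovered with 2 false calls among 48. With no change 0 were called. For the list test, a list shifted 2-fold was found among 28 and 0 others were called. The simulated noise was drawn independently for each probe set, with variances from limma's fitted prior. The filter was not applied again to the simulated values, so false calls that a filter by genotype may cause were not checked. These runs therefore check the scripts, and not the filter or the list calls where genes of a list are correlated.

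The alternatives were quantile normalization, median centring on the tested probe sets, an offset of 7.40 before log2 (the 20th percentile of all values), no filter, a 60th percentile filter, leaving out each array in turn, eBayes without the trend, robust hyperparameters and the replicate number as a block. Other thresholds (1.5-fold, 2.5-fold, adjusted p under 0.1), an estimated correlation and averaging of probe sets per gene were tried too. Scaling to the 18 bioB, bioC, bioD and cre hybridization control probe sets was added after seeing the data. A single gene or list counted as reversed only where its sign changed and it passed the threshold in either setting.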

Results

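Whole plants of the wild type gl1 and 35S::ZAT12 overexpressors, whose labels leave open whether the arrays hold 1 transgenic line or 2, were compared on 2 arrays each to ask how the transcriptome responds to ZAT12, a C2H2 zinc finger transcription factor, at 10 days of age without a stress treatment. Median signal over all 22810 probe sets lay between 40.8 and 41.4 on the 4 arrays. Over the 13701 tested probe sets, Pearson's r across probe sets, which are not independent replicates, was 0.974 between the wild type arrays and 0.959 between the 35S::ZAT12 arrays. It was between 0.911 and 0.929 for arrays of different genotypes. No 2 arrays held identical values for any probe set. The product of the transgene itself was not used as a check of the labels, because the gene table used here paired ZAT12 with 0 probe sets.

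In 35S::ZAT12 plants 3 anthocyanin genes rose together, while the defensin genes PDF1.2A and PDF1.2B, the thionin gene THI2.2 and the zinc finger gene ZAT5 fell steeply. In all, 263 probe sets were higher and 499 lower at a limma adjusted p under 0.05, and 546 of these 762 changed 2-fold or more (161 higher, 385 lower). Among the called probe sets with 1 gene, 107 were higher and 253 lower. The count without a variance estimate gave 343 probe sets (91 higher, 252 lower), of which 337 were also called. Without the filter it gave 994, more evenly divided (464 higher, 530 lower).

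The balance of higher and lower calls depended on the scaling. The 18 hybridization control probe sets were on average 1.53-fold lower on the 35S::ZAT12 arrays. Of these, 17 were lower on both 35S::ZAT12 arrays than on either wild type array. Scaling to them, chosen after seeing the data, moved the median log2 fold change of all tested probe sets from 0.04 to 0.66 and gave 1296 higher and 130 lower, since it added 0.62 to every log2 fold change. The 16 actin, GAPDH and ubiquitin control probe sets differed by between -0.42 and 0.11 (log2) in the deposited values, with a median of -0.07. Leaving out wild type replicate 1 lowered the count of calls to 362, and leaving out wild type replicate 2 lowered it to 504.

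**Figure D1:**
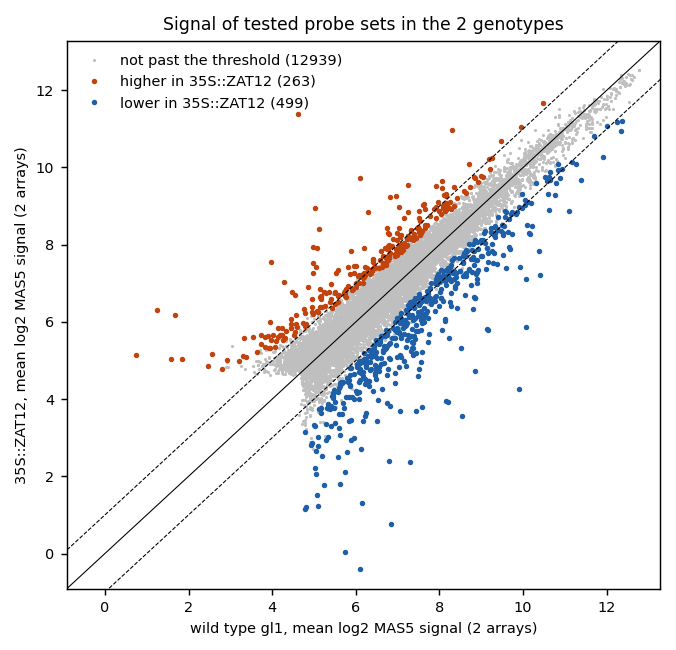
Mean log2 MAS5 signal of each of the 13701 tested probe sets in wild type (x axis) and 35S::ZAT12 (y axis), 2 arrays each. Red and blue points are the 263 higher and 499 lower probe sets past the threshold; the solid line marks equal signal and the dashed lines a 2-fold difference.

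Besides the anthocyanin genes described with their list, 9 further genes made up the 12 largest rises. AT4G23680 rose 15.3-fold, from 33.0 ± 8.56 in wild type to 496 ± 32.4 in 35S::ZAT12 (SD, n = 2 arrays each, as in all such pairs; limma adjusted p = 1.03e-05). AT4G12490, which encodes a lipid transfer family protein, rose 12.4-fold from 70.4 ± 21.9 to 894 ± 385 (adjusted p = 6.77e-05), and AT4G17470 rose 12.1-fold from 17.1 ± 9.46 to 189 ± 13.0 (log2 fold change 2.99 without wild type replicate 2, which was in the background). The basic helix-loop-helix gene AT2G31730 rose 5.89-fold from 31.6 ± 0.211 to 186 ± 18.1. Signals of AT1G59930, AT2G41380 and AT2G35390 were in the background in wild type and reached 79.5 ± 4.67, 36.2 ± 10.6 and 32.9 ± 1.86, which put them at least 8.42-fold, 3.75-fold and 3.49-fold higher. The AT1G59930 probe set is of a kind that can bind related sequences. The MATE transporter gene AT1G73700 rose from 6.67 ± 4.42 to 36.2 ± 8.42 and AT4G26600 from 7.01 ± 6.06 to 29.1 ± 4.07, each in the background on 1 wild type array, as AT4G17470 was. The calls of AT2G41380 and AT2G35390 ended when either 35S::ZAT12 array was left out (adjusted p between 0.0909 and 0.185). Those of AT1G73700 and AT4G26600 ended without the filter (adjusted p = 0.0869 and 0.175) and when either overexpressor array was left out. Without wild type replicate 2, the array in the background, their log2 fold changes were 1.87 and 1.36. AT4G26600 also missed the threshold without wild type replicate 2, after quantile normalization and without the trend.

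Among the 12 largest falls were PDF1.2B (AT2G26020) and PDF1.2A (AT5G44420), which encode plant defensins induced by jasmonate and ethylene. They fell 31.3-fold (378 ± 109 to 13.2 ± 8.32; adjusted p = 6.35e-05) and 18.5-fold (286 ± 19.5 to 18.22 ± 13.8; adjusted p = 0.000286). Their transcripts are near copies and the PDF1.2B probe set is of a kind that can bind related sequences, so the 2 values are not independent. Without 35S::ZAT12 replicate 1, which was in the background for PDF1.2B, that gene fell 19.4-fold. PDF1.2A fell 10.2-fold without 35S::ZAT12 replicate 1 and 33.6-fold without replicate 2. THI2.2 (AT5G36910), a thionin gene, went from 54.1 ± 7.29 to 4.30 ± 0.471, in the background, and was at least 4.999-fold lower. The glycine-rich protein gene AT2G05540 fell 49.4-fold from 988 ± 361 to 21.1 ± 11.9 (adjusted p = 1.79e-05), or 32.4-fold without 35S::ZAT12 replicate 2, which was in the background. AT1G19960 fell 19.3-fold from 298 ± 73.7 to 15.72 ± 5.63, and AT5G11070 fell 13.8-fold from 191 ± 26.3 to 13.8 ± 0.186.

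AT3G28270 was at least 10.7-fold lower (116 ± 16.2 against 1.91 ± 1.25), AT4G19430 at least 6.61-fold (73.2 ± 23.64 against 3.41 ± 3.29) and AT1G70985 at least 4.54-fold (48.9 ± 3.12 against 3.61 ± 1.24). For AT1G51090 and iqd33 (AT5G35670), a gene of the calmodulin-binding IQD family, the bounds were 2.55-fold and 2.61-fold. Their calls ended without a wild type array (AT1G51090 without either, adjusted p = 0.0993 and 0.0822; iqd33 without replicate 1, adjusted p = 0.111), and that of AT1G51090 also without the filter. PDF1.2B, ZAT5, AT2G05540 and AT5G11070 were in the background on 1 of the 2 overexpressor arrays. Of the 24 largest rises and falls, 18 stayed past the threshold in every setting in which they were tested. Among these, AT1G70985, AT4G19430 and THI2.2 were each tested in 12 of the 13 settings, because the stricter percentile filter left them out.

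**Figure D2:**
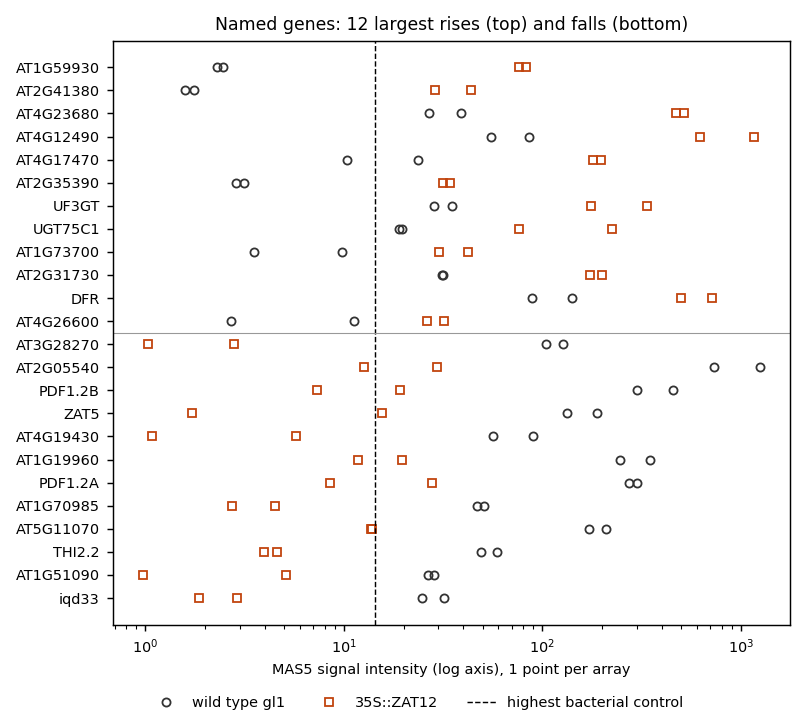
MAS5 signal intensity (log axis) of the 12 largest rises and 12 largest falls among one-gene probe sets, with 1 point per array (circles, wild type; squares, 35S::ZAT12). The dashed line is the highest bacterial control value on any array, 14.4. For each gene the points of one genotype lie apart from those of the other, and 9 genes were in the background on both arrays of the lower genotype.

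Probe sets without a name in the gene table changed as strongly, and which of them, if any, measures the ZAT12 transcript was not determined here. Probe set 247655_at rose 109-fold from 24.3 ± 0.351 to 2681 ± 447 (adjusted p = 1.24e-08), and 264400_at was at least 7.71-fold higher, a call that ended without 35S::ZAT12 replicate 1 (adjusted p = 0.0830). Among falls, 246633_at and 247573_at were at least 6.38-fold and 4.96-fold lower.

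All 3 tested members of the flavonoid and anthocyanin list rose, over all probe sets and adjusted over the list alone. DFR (AT5G42800), the dihydroflavonol reductase of anthocyanin synthesis, went from 115 ± 37.1 to 608 ± 155, a 5.33-fold rise (log2 fold change 2.41, SE 0.25, adjusted p = 0.000294). UF3GT (AT5G54060) and UGT75C1 (AT4G14090) encode anthocyanin glycosyltransferases. UF3GT rose 7.68-fold from 31.9 ± 4.70 to 256 ± 113 (adjusted p = 0.000277) and UGT75C1 6.74-fold from 19.4 ± 0.490 to 150 ± 104 (adjusted p = 0.00308). The 35S::ZAT12 arrays differed for UGT75C1 (224 and 76.3), and both lay above the wild type arrays (19.0 and 19.7). Its log2 fold change was 1.98 without 35S::ZAT12 replicate 1 and 3.53 without replicate 2. The list's median log2 fold change was 2.75 (camera adjusted p = 2.71e-06 with the preset correlation; adjusted p = 0.602 with an estimated correlation). The other 10 genes of this list were not analysed here.

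Both tested members of the jasmonate and ethylene list were the PDF1.2 genes, which fell as above, also adjusted over the list alone. In the list of C1-2i zinc finger genes, the subfamily of ZAT12, ZAT5 (AT2G28200) fell from 160 ± 39.0 to 8.67 ± 9.82 (adjusted p = 0.00321). The size of this fall rests on an array in the background. It was 10.1-fold without 35S::ZAT12 replicate 2 (1.73, in the background) and 30.3-fold from both arrays. ZAT10 had 51.3 ± 9.09 in wild type and 30.2 ± 10.3 in 35S::ZAT12, which did not pass over all probe sets (adjusted p = 0.196). Adjusted over the list alone, both counted as lower (limma adjusted p = 8.26e-05 and 0.0315).

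Of 3 tested cold-regulated genes, COR47 (AT1G20440), which encodes a dehydrin, fell 2.32-fold from 737 ± 69.1 to 318 ± 15.5 (log2 fold change -1.21, SE 0.17, adjusted p = 0.00215). This call ended after scaling to the hybridization controls (log2 fold change -0.59, adjusted p = 0.244). COR15B (35.5 ± 15.8 and 41.4 ± 7.25) and LTI30 (95.9 ± 26.7 and 97.3 ± 62.9) did not pass. The count adjusted over the list alone was 1 lower as well, and the list did not pass camera (adjusted p = 0.266, median log2 fold change -0.12) except without 35S::ZAT12 replicate 1 (adjusted p = 0.0442, median -0.83). None of the 3 tested members of the list of reactive oxygen genes passed, over all probe sets or adjusted over the list alone. The list holds 21 genes, and its other members were not analysed here. SAPX, TAPX and GR1, which encode the stromal and thylakoid ascorbate peroxidases and glutathione reductase, had log2 fold changes of -0.11, -0.03 and -0.02 with SEs of 0.19, 0.21 and 0.18.

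In the circadian clock list the 1 tested gene, GI (GIGANTEA, AT1G22770), rose 2.19-fold from 39.1 ± 8.30 to 85.0 ± 9.93 (adjusted p = 0.0312). GI had an unadjusted limma p of 0.00126, which adjustment over a list with 1 tested member leaves unchanged. Its call ended without the filter, without wild type replicate 2 and without 35S::ZAT12 replicate 1 (adjusted p between 0.0736 and 0.176). Among photosynthesis genes 0 of 3 passed over all probe sets, and PORB, a protochlorophyllide reductase gene, passed adjusted over the list alone (adjusted p = 0.0158). PORB had 1011 ± 289 in wild type and 1689 ± 162 in 35S::ZAT12, with an adjusted p of 0.0736 over all probe sets, 0.0228 after quantile normalization and 0.0269 after scaling to the hybridization controls. RCA and LHCB4.1 had log2 fold changes of -0.36 and -0.04. The list's median was -0.04 while its mean was 0.12 and its camera direction was up (adjusted p = 0.766).

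EXPA8, an expansin gene of the cell wall list, fell 2.25-fold from 448 ± 76.3 to 211 ± 103 (adjusted p = 0.0403), while EXPA4 did not pass (426 ± 53.1 and 337 ± 8.58). In the root marker list the root hair expansin gene EXPA18 fell 2.46-fold from 49.7 ± 7.85 to 20.2 ± 2.21 (adjusted p = 0.0330). EXPA7 (38.1 ± 12.4 and 19.8 ± 13.0, in the background on 1 overexpressor array) and PYK10 (2294 ± 428 and 2185 ± 106) did not pass. These counts were the same adjusted over the lists alone. The root marker list had a median log2 fold change of -1.08 and did not pass camera (adjusted p = 0.125). It passed after scaling to the hybridization controls (adjusted p = 0.0429) and without 35S::ZAT12 replicate 1 (adjusted p = 0.0442). The EXPA8 call ended without the filter or the trend, after scaling to the hybridization controls, without wild type replicate 1 and without 35S::ZAT12 replicate 1. The EXPA18 call ended without the filter, after the same scaling and when any 1 array was left out.

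None of the tested members passed in the early stress list (WRKY53, log2 fold change -0.79, and WRKY6, 0.46), the iron list (PYE, 0.41) and the salicylic acid list (SAG101, 0.07), over all probe sets or adjusted over the lists alone. The reference genes SAND (0.45), UBC21 (-0.07) and TIP41L (0.04) did not pass either, with a camera adjusted p of 0.674 for their list and 0 calls adjusted over the list alone. Members of the CBF/DREB1, abscisic acid, heat shock and senescence lists were not analysed here.

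**Figure D3:**
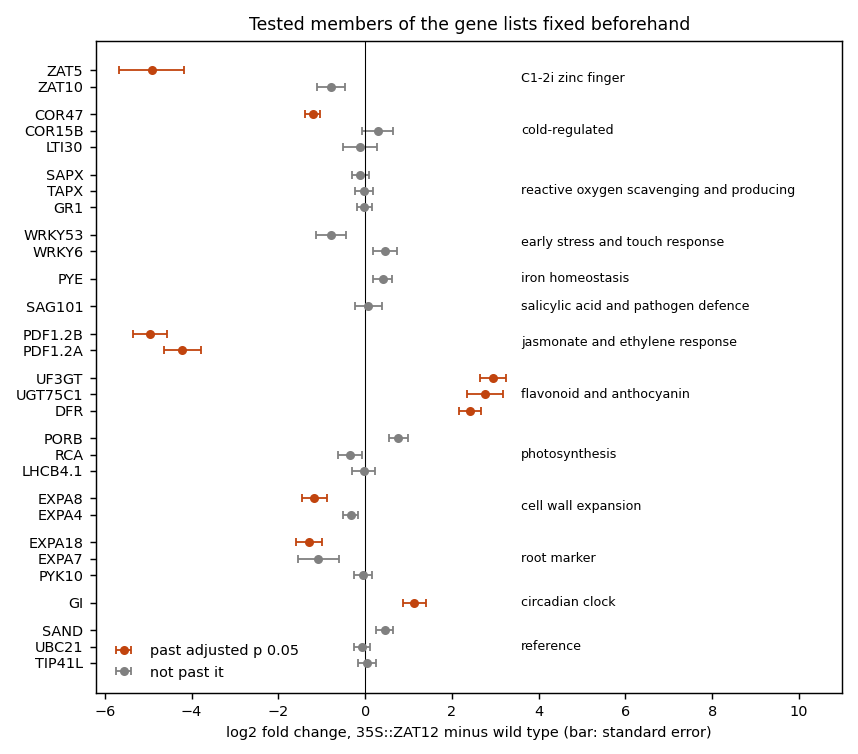
Log2 fold change (35S::ZAT12 minus wild type, x axis) of the 29 tested members of the gene lists fixed beforehand, with limma's standard error as bars. Members past an adjusted p of 0.05 are red and the others grey; the 3 anthocyanin genes lie between 2.41 and 2.94 and the PDF1.2 genes at -4.97 and -4.21.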

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

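Scaling to the hybridization controls was chosen after seeing the data; every other alternative was planned. Against 762 probe sets past the threshold, no filter gave 460 (22746 probe sets were then tested), the hybridization control scaling 1426, an adjusted p under 0.1 1207 and leaving out 1 array in turn 362 to 895, where the lone array of a genotype is assumed to vary like the other genotype. With the replicate number as a block (replicate block) the count was 1564, with 643 higher and 921 lower, and held all 762. It also brought PORB (adjusted p = 0.000484) and the defensin family (4.09e-07) past the threshold. Same-numbered arrays are not shown to be paired: across probe sets their deviations from the genotype means correlated at 0.06, with only 2 numbers. The other settings gave 552 to 791. Of the 762, 705 were shared with quantile normalization, 731 with median centring and 389 with the hybridization control scaling.

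The count of 343 probe sets 2-fold apart in all pairs became 994 without the filter (464 higher, 530 lower), 537 with the hybridization control scaling (457 higher, 80 lower), 942 at 1.5-fold, 172 at 2.5-fold and 551 to 721 without 1 array, when only 2 pairs remain. Of 28 lists, 6 passed with the preset correlation, 0 with an estimated one (0 at an unadjusted camera p under 0.05, against 8 with the preset one) and 5 to 9 without 1 array. The causes of these moves were not tested except where stated. No named gene past the threshold changed sign and no list past it changed its camera direction in any setting run. Under the hybridization control scaling 3 of the 32 named genes and unnamed probe sets past the threshold lost their calls, and 9 not past it changed sign. Robust hyperparameters were not run for lists. Signal near the bacterial controls limits folds to bounds for 26 called probe sets.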

Other observations

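Gene families defined by symbol were tested too, and some share members with the lists fixed beforehand. Of 22 families, 5 passed camera at the preset correlation and 0 with an estimated one, and most members did not pass singly. The estimated version rests on 2 residual degrees of freedom, so its lack of calls does not show that correlation accounts for the others. The estimated correlation was 0.79 for the flavonoid and anthocyanin list and 0.46 for tetrapyrrole synthesis genes. It was 0.25 for tubulin and actin genes and 0.22 for chloroplast-encoded genes. These lie above the preset 0.01, which may make the preset camera p-values of these lists too small. For RALF peptide genes it was -0.093 and for the expansin and xyloglucan endotransglucosylase family -0.015, both below the preset. The unadjusted camera p of the expansin and xyloglucan endotransglucosylase family still rose from 0.00128 to 0.0745. Among 67 tested chloroplast-encoded genes 7 rose and 0 fell, with a median log2 fold change of 0.40 (camera adjusted p = 1.17e-06; adjusted p = 0.602 with an estimated correlation). Adjusted over the list alone, 12 rose. They included rpoA, a chloroplast RNA polymerase gene (326 ± 17.8 to 721 ± 111, SD, n = 2), and the ribosomal protein gene rps2 (181 ± 9.05 to 430 ± 163). The median was 0.14 without 35S::ZAT12 replicate 1 and 0.74 without 35S::ZAT12 replicate 2. The tetrapyrrole synthesis family had a median of 0.53 over 9 genes (camera adjusted p = 0.00374, and adjusted p = 0.602 with an estimated correlation). Of these GSA1 rose (289 ± 36.4 to 493 ± 60.5), and 6, with PORB of the photosynthesis list among them, rose adjusted over the list alone. The 9 include UPP (log2 fold change 0.43), picked up by its symbol, which is not a tetrapyrrole synthesis gene and was not among the 6. The camera call of this family ended without wild type replicate 1 (adjusted p = 0.103).

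Expansin and xyloglucan endotransglucosylase genes had a median of -0.33 in the deposited values and 0.28 after scaling to the hybridization controls (16 genes, 0 rose and 3 fell, 4 adjusted over the list alone; camera adjusted p = 0.00716, direction down under both scalings; adjusted p = 0.602 with an estimated correlation). Camera compares a family with the other genes tested. A direction kept after 0.62 was added to every log2 fold change is therefore no further evidence of a fall. EXPA8 and EXPA18, already given with the fixed lists, are 2 of the 3 falls. The family's call ended without 35S::ZAT12 replicate 2 (adjusted p = 0.0503). Tubulin and actin genes had medians of -0.34 and 0.28 (8 genes, 1 fell, 3 adjusted over the list alone; camera adjusted p = 0.00716, and adjusted p = 0.602 with an estimated correlation). This call ended after that scaling (adjusted p = 0.0620) and without wild type replicate 2 (adjusted p = 0.0868). RALF peptide genes had medians of -0.46 and 0.15 (6 genes, 1 fell, 3 adjusted over the list alone; camera adjusted p = 0.0223, and adjusted p = 0.602 with an estimated correlation). Here the call ended after that scaling (adjusted p = 0.117), without the filter (adjusted p = 0.128) and without wild type replicate 1 (adjusted p = 0.164). EXPB3 fell from 417 ± 22.8 to 166 ± 13.1, TUB1 from 105 ± 5.04 to 39.7 ± 6.89 and RALFL32 from 191 ± 18.5 to 97.7 ± 21.1. The other 17 families did not pass camera in the main setting, and in the auxin, beta-glucosidase and SWEET families median, mean and camera direction differed in sign. The defensin and cysteine-rich family, whose 2 falls are the PDF1.2 genes (adjusted p = 0.187, median -0.12), passed, direction down, after scaling to the hybridization controls (adjusted p = 1.42e-06, median 0.50), with the 60th percentile filter (0.00186), without either wild type array (4.36e-05 and 0.000177) and without 35S::ZAT12 replicate 1 (0.0318). The glutathione transferase family passed without the filter (adjusted p = 0.00854). Among single members PDF2.1 rose 4.19-fold (16.4 ± 7.98, in the background on 1 wild type array, to 64.6 ± 8.67) while both PDF1.2 genes fell, and the auxin-responsive gene GH3.3 rose 3.01-fold while GH3.17 fell 2.05-fold. Glycosyltransferase genes of flavonoids parted, with UGT78D2 up 1.79-fold and UGT78D1 down 2.34-fold. The serine carboxypeptidase-like genes SCPL27 and scpl26 fell 3.54-fold and 2.88-fold.

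Other genes were picked after their values were seen. AT5MAT, an anthocyanin malonyltransferase gene outside the fixed list, rose from 27.4 ± 0.0580 to 75.1 ± 4.07 (adjusted p = 0.00830). The glycosyl hydrolase genes GH9B13, GH9B7 and GH9C1 (in the background on 1 overexpressor array) fell, with GH9B13 going from 474 ± 21.6 to 128 ± 8.56 (adjusted p = 0.000164). GAMMA-VPE, a vacuolar processing enzyme gene, fell from 1549 ± 1.84 to 643 ± 58.8. SPCH, which encodes a factor of stomatal lineage entry, rose from 22.0 ± 1.16 to 62.4 ± 13.6.

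The test with the hybridization controls was chosen after the excess of falls had been seen, and the other tests before. Falls made up 65.5% of calls. In the brightest 25% of tested probe sets 159 of 243 calls were falls (65.4%, 95% exact interval 59.1 to 71.4). The excess of falls was therefore not confined to dim probe sets. The interval treats probe sets of the same arrays as independent, which they are not, so it is too narrow. Whether noise of dim probe sets added to the excess was left open. Array scaling stays open: the share was 67.0% or more after median centring and quantile normalization, but both keep the arrays' centres alike, as the deposited scaling does, and moved the median log2 fold change by at most 0.04, so the bound set beforehand excludes nothing. An unequal amount of labelled RNA against the hybridization controls stays open too, since the share of 9.12% after scaling to them follows from adding 0.62 to every log2 fold change whatever the cause, and the controls were uneven within wild type (geometric means 660 and 467, against 345 and 380). A response to the transgene was not tested apart from these.

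Signal under the 20th percentile on both arrays of one genotype and above the 60th on both of the other was seen for 3 probe sets, among them AT3G28270 and AT1G59930, whose probe set can bind related sequences. The other 2 splits of the arrays, which mix the genotypes, gave at most 0 such probe sets, and 3 splits are too few for a share under 0.05. A linked chromosome segment, as between lines of different origin, cannot be told apart from an effect of the transgene: each of the 2 named genes is 50% of the set, so the window test had no power.

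Some neighbouring genes were called together. Neighbours here are genes that follow each other among the tested, named nuclear genes. Unnamed or untested genes can lie between them, as for the counted pair AT1G29530 and AT1G29660. Among 7177 nuclear genes tested, 17 adjacent pairs changed the same way (10.1 expected, 95th percentile of 10000 random draws 15, and 2.33% of draws had at least as many, read one-sided) and 5 in opposite directions (6.86 expected, 95th percentile 11). An excess of same-way pairs alone is what shared or cross-hybridizing probes could give, as for AT4G12490 and AT4G12500, which rose 12.4-fold and from 59.2 ± 2.52 to 229 ± 29.1. Shared regulation of neighbouring genes would give it as well and was not tested. Of the 17 pairs, 0 held a probe set marked by the array design as shared between transcripts. Probe sets paired with several genes had been left out of this count, so the 0 does not argue against cross-hybridization.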
